A study of Homo sapiens with 12 samples.

How the data were processed

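RNA-seq of K562 cells in 4 groups of 3 labelled biological replicates was re-analysed from the deposited table of FPKM values, with 1 column per library. Per the labels' protocols, RNA was extracted with Trizol and sequenced in single reads of 50 bases on an Illumina HiSeq. Per the submitters' processing notes, the authors used Bowtie2 2.2.9, TopHat2 2.0.14 and Cufflinks with the genome build hg38. The version of Cufflinks and the annotation release are not given in the sources used here. The deposited FPKM values are fragments scaled to locus length and to the mapped fragments of the library, as Cufflinks gives them, and no further scaling between libraries is stated. The table holds 38272 loci with identifiers of a merged assembly. Of these, 9035 have no gene name, 839 carry several names, and 4814 of the 18731 symbols occur on more than 1 locus. Reads from overlapping or antisense genes and from near-identical copies cannot be separated in these values.

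Depth was estimated from the values. Where low values of a locus across libraries stepped in whole multiples of 1 read (tolerance 0.03), reads were recovered, which held for 19103 of 37506 loci (50.9%) and for 5 loci with decoy depth factors. The recovered loci are mostly those with few reads, so read numbers are given for such loci only, and the total depth is unknown. No count-based test was run.

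Values were transformed as log2(FPKM + 1), and loci with at least 1 FPKM in at least 3 of the 12 libraries were tested (32866). A linear model with 1 mean per group was fitted over all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. The comparisons were TNF against control, SG against control, TNFSG against TNF, TNFSG against SG, and the interaction of the treatments. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and lists with under 5 tested members are given by values only. The 19 lists cover the lncRNA locus, NF-kB targets, TNF receptor signalling, immediate early genes, interferon-stimulated genes, erythroid, megakaryocyte and myeloid genes, apoptosis, p53 targets, G1/S and G2/M genes, the integrated stress response, endoplasmic reticulum chaperones, heat shock, cholesterol synthesis, histones, mitochondrially encoded genes and RNA silencing. Markers of lymphoid, fibroblast, epithelial and endothelial cells were checked as further lists.

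The genes named in the text follow a rule fixed before the data were examined. It takes every measured member of the lncRNA locus list, then in each pairwise comparison up to 10 rises and 10 falls of largest size among adjusted p values under 0.05 with no overlap of replicate values and a mean of at least 2 FPKM in the higher group (5 and 5 in the interaction). It adds up to 4 members of lowest p per list, and where fewer than 5 loci pass, the 5 of lowest p as values only. CD46, TDG, UBE2K, MFN1, PEA15, UTP6, APPL1, SLC39A14, CERS2 and NEK9 were named after their values were seen, because they changed in both comparisons of the targeted transfection. POLR1B, RRP1B, B2M, ERAP2, CYP3A5 and the globins HBZ, HBE1, HBG2 and HBG1 were also named after their values were seen. In TNFSG against SG, 1 few-read non-coding locus taken by the rule is left unnamed, and its call was lost in 6 of the 6 fits that left out a library.

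The alternatives fixed beforehand were the replicate number as a block, pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, limma without the trend, only the groups compared in the fit, and each library left out in turn. For the lists they were camera with an estimated correlation and fry. Robust empirical Bayes, a restriction to protein-coding genes and the removal of loci averaging under 10 recovered reads were chosen after seeing the data. Sites of 7 bases in 3 prime UTRs were taken from GENCODE release 29 for 8519 protein-coding genes at 5 FPKM or more. A trend of the fold changes on length, GC content and mean FPKM was removed before sites were compared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Figures were drawn with matplotlib 3.10.9.

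The model was tested on simulated data with 200 loci changed by known amounts in the values of each comparison. At a log2 change of 1 it recovered 37.3% of changed loci in TNF against control, 35.8% in SG against control, 34.3% in TNFSG against TNF, 25.4% in TNFSG against SG and 16.4% in the interaction. At a log2 change of 2 it recovered 62.1%, 66.7%, 50.0%, 51.5% and 36.4% in the same order. False calls were 6.41%, 6.10%, 10.0%, 1.67% and 2.78% of the calls. The simulation was run once per comparison, with independent normal noise for each locus and changes only in loci with a mean log2 value above 1. It had no whole-read steps and no effect shared by replicates or genes. Its rates therefore do not describe calls of few-read loci in the real data. The site test ranked a planted site first in 5 of 5 simulated runs.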

Results

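RNA was sequenced from K562, a chronic myeloid leukaemia cell line, in 12 libraries that form 4 groups of 3 labelled biological replicates. The control group received a non-targeting siRNA together with a non-targeting GapmeR, an antisense oligonucleotide that directs RNase H to its target. The SG group received an siRNA and a GapmeR against a long non-coding RNA (lncRNA). The TNF group was the control transfection followed by tumour necrosis factor alpha (TNF) at 20 ng/mL for 6 hours, and the TNFSG group was the targeted transfection followed by the same treatment. Reads were single and 50 bases long. The table gave FPKM for 38272 loci, of which 32866 were tested, and 9035 loci had no gene name. Read totals were not in the file. Where values stepped in whole reads, the relative depths of the libraries lay between 0.88 (control replicate 3) and 1.346 (TNFSG replicate 1), and FPKM sums lay between 925955 and 1083476. Values are given below as mean FPKM ± SD with n = 3 per group, and fold changes are on the log2(FPKM + 1) scale, which understates the change of loci with low values.

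The series title places the lncRNA by the name PPTG1, read here as PTTG1, so the loci around PTTG1 on chromosome 5 were examined first. The locus named MIR146A lay at 0.36 ± 0.20 FPKM in control, 25 ± 3.5 in TNF, 0.040 ± 0.035 in SG and 5.44 ± 2.03 in TNFSG. Its values were 28.1, 25.6 and 21.2 FPKM in the TNF libraries and 7.77, 4.51 and 4.03 FPKM in the TNFSG libraries, so the groups did not overlap. In control its values were 0.36, 0.569 and 0.159 FPKM, and in SG they were 0, 0.057 and 0.063 FPKM. The change was 4.25 ± 0.22 (log2, SE) for TNF against control with a limma adjusted p of 1.2e-05, and -2.05 ± 0.22 for TNFSG against TNF with a limma adjusted p of 0.0191. The latter call was lost when any of 5 of the 6 libraries was left out (all but TNFSG replicate 1), with limma adjusted p values up to 0.0831, and its log2 change then lay between -2.16 and -1.89. It was also lost with a pseudocount of 0.1 (0.0968) and with only the groups compared in the fit (0.214), and over all alternatives the adjusted p of this fall ran from 0.00653 to 0.214. Without TNF the mean was 89.0% lower in SG than in control, and the log2 change depended on the pseudocount: -0.38 ± 0.22 with 1 (limma adjusted p 0.628), -0.65 with 0.5 and -1.65 with 0.1 (0.198). GENCODE release 29 (hg38) places MIR146A at 160485352 to 160485450 on chromosome 5, inside exon 2 of the host transcript MIR3142HG, which spans 160438594 to 160487426. The file gives no coordinates for its loci, so whether the locus named MIR146A is the targeted lncRNA rests on this reading of the title.

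PTTG1 itself lay at 192 ± 11 FPKM in control, 204 ± 5.83 in TNF, 182 ± 6.49 in SG and 196 ± 7.18 in TNFSG. Its neighbour SLU7 lay at 19.4 ± 2.33, 21.7 ± 0.84, 19.0 ± 0.98 and 23.0 ± 2.45 FPKM in the same order. None of PTTG1, SLU7, PWWP2A, ATP10B, ZBED8, CCNJL and FABP6 passed limma's adjusted threshold of 0.05 in any of the 5 tests. Among the 8 tested loci of this list, 1 reached an unadjusted p under 0.05 in TNF against control, 1 in SG against control and 2 in each of the other pairwise comparisons. CCNJL and FABP6 varied widely between replicates, with 6.88 ± 6.17 and 18.5 ± 11 FPKM in control.

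**Figure D1:**
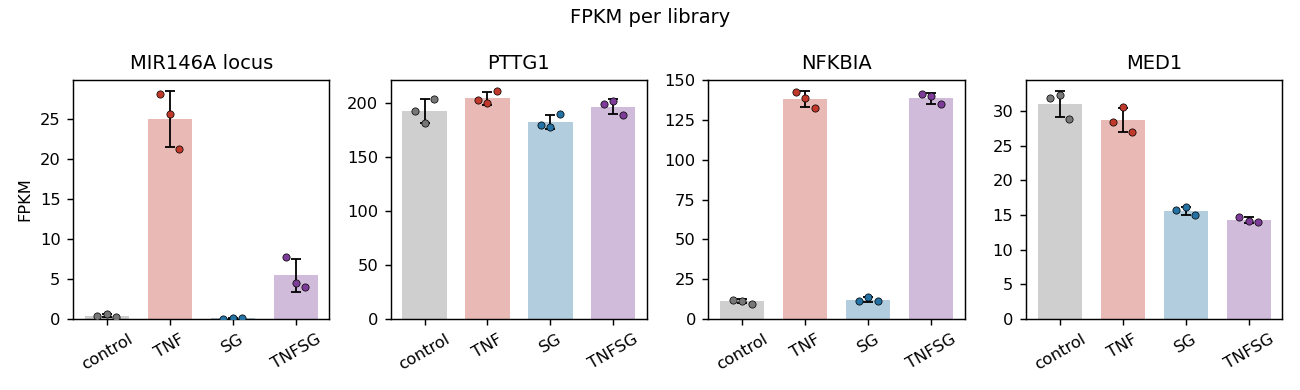
FPKM of 4 loci (vertical axis) in the 4 groups (horizontal axis), with points for the 3 libraries, bars for the mean and lines for 1 SD. The MIR146A locus rose from 0.36 to 25 FPKM with TNF and reached 5.44 FPKM in TNFSG, PTTG1 lay between 182 and 204 FPKM in all groups, NFKBIA rose with TNF in both transfections, and MED1 was lower in SG and TNFSG.

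The comparison of TNF with control measured the TNF response of mock-transfected cells. ICAM1 rose from 15.1 ± 0.55 to 339 ± 13.0 FPKM, a change of 4.40 ± 0.09 (log2, SE) with a limma adjusted p of 2.42e-08. CXCL8 rose from 11.2 ± 0.71 to 138 ± 7.93 FPKM, NFKBIA from 10.9 ± 1.27 to 138 ± 4.98 FPKM and CD83 from 3.86 ± 0.24 to 75.9 ± 4.57 FPKM, each with a limma adjusted p of 1.29e-07. CXCL10 rose from 0.27 to 31.1 FPKM, CXCL1 from 0.70 to 32.5 FPKM, RRAD from 0.61 to 25.2 FPKM and LTB from 0.85 to 73.4 FPKM. NFE2, an erythroid transcription factor, fell from 99.1 ± 3.60 to 50.0 ± 6.87 FPKM, a change of -0.98 ± 0.13 with a limma adjusted p of 0.00541. HK2 fell from 20.1 to 9.48 FPKM and RAB3IL1 from 16 to 7.57 FPKM. The HK2 and RAB3IL1 calls were each lost without control replicate 2, control replicate 3, TNF replicate 1 or TNF replicate 2, with limma adjusted p values up to 0.108 and 0.0932. The non-coding gene RP11-132A1.4 fell from 18.9 to 10.1 FPKM. The remaining loci among the largest changes averaged 6.08 reads per library or fewer: PCBP3, AC002310.7, PRSS23 and RP11-875O11.2 were listed at 0 in all control libraries and above 0 in all TNF libraries, and C2orf47, TAF1, SHCBP1, LINC00894, RARRES1 and WIPF1 fell. With single libraries left out, the LINC00894 and WIPF1 calls were lost in 6 of 6 fits, the C2orf47, TAF1 and RARRES1 calls in 5 and the SHCBP1 call in 3, with limma adjusted p values up to 0.177. In all, 387 loci rose and 91 fell at a limma adjusted p under 0.05, of which 246 changed by at least 1 on the log2 scale and 35 averaged under 10 reads.

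Among the gene lists, 47 of 64 tested NF-kB target genes rose in TNF against control and 59 rose and 1 fell adjusted over the list alone, with a camera adjusted p of 7.02e-106 and a median change of 1.85. Of 39 interferon-stimulated genes 8 rose (13 adjusted over the list alone; camera adjusted p 4.18e-11), led by TAP1 from 1.00 to 10.7 FPKM, OAS3 from 0.905 to 5.78 FPKM, IFIT3 from 1.62 to 7.32 FPKM and DTX3L from 3.67 to 6.58 FPKM. Of 28 apoptosis genes 5 rose (9 rose and 1 fell adjusted over the list alone; camera adjusted p 1.88e-06), among them PMAIP1 from 25.3 to 56.2 FPKM, BBC3 from 7.42 to 16.9 FPKM and TNFRSF10B from 8.86 to 19.8 FPKM. With an estimated correlation between genes, the calls of these 3 lists held, with camera adjusted p values of 0.000896, 0.0365 and 0.00825. Of 26 immediate early genes 8 rose (9 rose and 1 fell adjusted over the list alone; camera adjusted p 4.53e-09, and 0.191 with the estimated correlation), including JUNB from 30 to 79.2 FPKM, BTG2 from 25.1 to 77.8 FPKM, JUN from 13.6 to 27.9 FPKM and KLF10 from 14.8 to 23.3 FPKM. The KLF10 call was lost without TNF replicate 3 (limma adjusted p 0.0534). Of 22 p53 target genes 5 rose and 1 fell (camera adjusted p 5.62e-06, and 0.191 with the estimated correlation), with GADD45A rising from 93.1 to 142 FPKM. K562 lacks functional p53, so these rises are not read as a p53 response. BTG2, BBC3 and TNFRSF10B are on this list as well as on the immediate early or apoptosis list, so these list results overlap.

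Of 23 TNF receptor signalling components CYLD, CFLAR and IKBKB rose, and the camera adjusted p was 0.0335 (0.119 with the estimated correlation). CYLD rose from 1.34 to 4.95 FPKM, IKBKB from 17.9 to 32.0 FPKM and CFLAR from 46.4 to 110 FPKM, and the CFLAR call was lost without control replicate 3 (limma adjusted p 0.0535). The list's call was lost without control replicate 2, TNF replicate 1 or TNF replicate 2, with camera adjusted p values up to 0.0838. Of 47 erythroid genes TMCC2 rose from 2.04 to 6.86 FPKM while NFE2 and SLC25A38 fell, with a camera adjusted p of 0.00381 for lower values (0.715 with the estimated correlation). That call was lost without control replicate 3 (0.135) or TNF replicate 1 (0.372). SLC25A38 fell from 23.6 to 16.1 FPKM, and RUNX1 in the megakaryocyte list fell from 10.1 to 6.32 FPKM. The RUNX1 call was lost when any of the 6 libraries was left out and the SLC25A38 call in 4 of these 6 fits, with limma adjusted p values up to 0.106 and 0.1. The TMCC2 call was lost without control replicate 2 or control replicate 3, with limma adjusted p values up to 0.0656. Of 25 integrated stress response genes SESN2, DDIT4 and PPP1R15A rose, to 40.7, 237 and 39.9 FPKM, and the list's camera adjusted p was 0.193. DDIT4 and PPP1R15A each lost their call in 4 of the 6 fits that left out a library. RFC2 rose from 56.2 to 73.5 FPKM in the list of G1/S and DNA replication genes, whose camera adjusted p was 0.749.

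The comparison of TNFSG with SG measured the TNF response of cells that had received the siRNA and GapmeR against the lncRNA. ICAM1 rose from 16 ± 1.7 to 361 ± 33.9 FPKM, a change of 4.41 ± 0.09 (log2, SE) with a limma adjusted p of 2.37e-08. NFKBIA rose from 12 to 139 FPKM, CXCL8 from 10.2 to 123 FPKM and CD83 from 5.08 to 83.3 FPKM. CXCL1 rose from 0.80 to 50.7 FPKM, CXCL10 from 0.25 to 29.7 FPKM and LTB from 0.59 to 54.8 FPKM, while SLC2A6 was listed at 0 in all SG libraries and averaged 20.5 FPKM in TNFSG. The MIR146A locus rose by 2.59 ± 0.22, with a limma adjusted p of 0.000271. NFE2 fell from 100.1 to 44.8 FPKM, a change of -1.16 ± 0.13 with a limma adjusted p of 0.00204. RAB3IL1 fell from 15.1 to 6.11 FPKM and SLC25A38 from 27.0 to 17.1 FPKM. FAM90A1 and THEM4 also fell, and their calls were lost in 6 and 5 of the 6 fits that left out a library, with limma adjusted p values up to 0.148 and 0.163. In all, 449 loci rose and 91 fell at a limma adjusted p under 0.05, of which 66 averaged under 10 reads. These few-read loci included SDCBPP3, C16orf96, PCBP3 and FTX among the largest rises, and AC012322.1, RP11-234B24.6, RP4-676J13.2, RP11-348J24.2, CSPG4 and RALGAPA2 among the largest falls. The calls of FTX, RP11-234B24.6, RP11-348J24.2, CSPG4 and RALGAPA2 were each lost in 5 of the 6 fits that left out a library, with limma adjusted p values up to 0.148. The locus shared by DYNLL2 and RP11-159D12.8 rose from 12.6 ± 1.97 to 472 ± 345 FPKM, and its call was lost in 5 of the 6 fits that left out a library, with a limma adjusted p up to 0.0805.

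Of 64 NF-kB target genes 50 rose in TNFSG against SG and 60 rose adjusted over the list alone (camera adjusted p 1.85e-108, and 0.00082 with the estimated correlation). Of 39 interferon-stimulated genes 10 rose (12 adjusted over the list alone; camera adjusted p 1e-11, and 0.0313 with the estimated correlation), among them IFIH1 from 0.579 to 4.99 FPKM and TAP1 from 1.21 to 13.0 FPKM. Of 28 apoptosis genes 5 rose (7 adjusted over the list alone; camera adjusted p 0.000117, and 0.0253 with the estimated correlation), including BCL2L1 from 67.4 to 115 FPKM and PMAIP1 from 23.0 to 55.3 FPKM. Immediate early genes (8 of 26 rose, and 9 rose and 1 fell adjusted over the list alone; camera adjusted p 2.33e-08), p53 target genes (5 rose and 1 fell of 22; 0.00133), erythroid genes (1 rose and 2 fell of 47; 0.000176 for lower values) and the list of the lncRNA locus (1 of 8 rose; 0.00435) passed camera's preset correlation. With the estimated correlation their adjusted p values were 0.308, 0.481, 0.671 and 0.056. Of the TNF receptor signalling components CYLD and IKBKB rose, and of the integrated stress response genes SESN2 and PPP1R15A rose, with camera adjusted p values of 0.496 and 0.458 for the lists. RUNX1 fell from 9.75 to 5.73 FPKM and RFC2 rose from 64.9 to 82.2 FPKM. With single libraries left out, the SESN2 and RFC2 calls were lost in 6 of 6 fits, the PPP1R15A call in 5 and the RUNX1 call in 3, with limma adjusted p values up to 0.131, 0.0817, 0.129 and 0.0562.

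The TNF responses of the mock-transfected and the targeted cells were compared across genes over comparisons that share no library. Of the loci that rose, 317 rose in both comparisons, where independent lists would share 5.29, and 47 fell in both, where independent lists would share 0.252. The fit gave both comparisons the same error per locus, so their calls are not independent and these expected numbers are only a reference. Over the 652 loci changed in either comparison, 94.9% changed in the same direction, as did 63.1% of all loci tested. The fold changes had a Spearman correlation of 0.784 and a Pearson correlation of 0.593 across genes, which are not independent replicates. With loci averaging under 10 reads left out before testing, a setting chosen after the data were seen that also calls other loci because 20213 share the adjustment, the correlations over the 913 loci then changed in either comparison were 0.894 and 0.881.

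**Figure D2:**
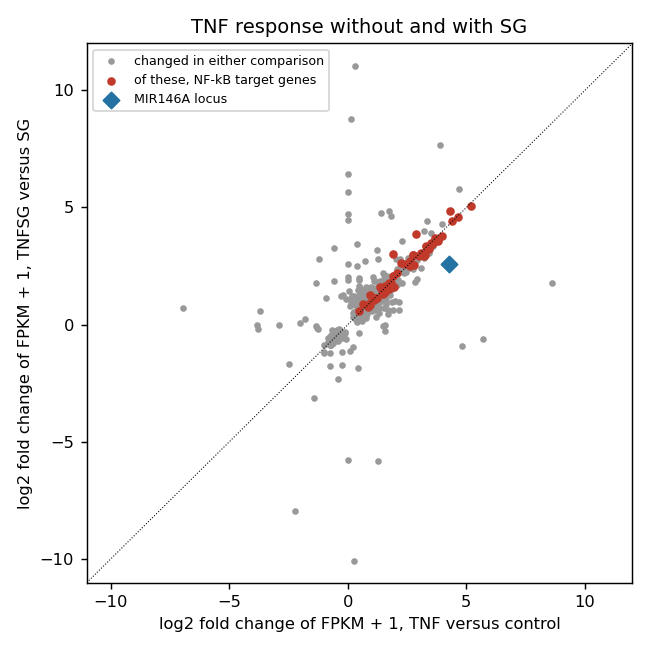
Log2 fold change of FPKM + 1 in TNF versus control (horizontal axis) and in TNFSG versus SG (vertical axis) for the 652 loci changed in either comparison, 1 point per locus. NF-kB target genes (red) lie near the dotted line of equal change, and the MIR146A locus (blue diamond) lies at 4.25 and 2.59.

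The comparison of SG with control measured the effect of the siRNA and GapmeR in cells without TNF. MED1, a subunit of the Mediator complex, fell from 31.0 ± 1.84 to 15.6 ± 0.56 FPKM, a change of -0.95 ± 0.07 (log2, SE) with a limma adjusted p of 0.00203. The locus shared by DNAJC25 and GNG10 fell from 50.1 ± 4.80 to 26.1 ± 1.10 FPKM and CAV2 from 20.7 ± 0.45 to 11.3 ± 0.84 FPKM, with limma adjusted p values of 0.00365 and 0.00436. SEC11A, a subunit of the signal peptidase, rose from 95.9 ± 5.32 to 171 ± 9.26 FPKM, a change of 0.83 ± 0.08 with a limma adjusted p of 0.00436. These 4 calls held whichever library was left out. SHOC2 fell from 11.6 to 4.35 FPKM, HEATR1 from 53.3 to 27.0 FPKM, PTPN12 from 39.5 to 22.7 FPKM and FBXO28 from 20.7 to 11.4 FPKM, and UBE2L6 rose from 5.60 to 11.6 FPKM and CRTC1 from 8.14 to 14.5 FPKM. These 6 calls were each lost in 4 to 6 of the 6 fits that left out a library, with limma adjusted p values up to 0.0923 for HEATR1 and up to 0.207 for FBXO28. IQSEC3, CPLX1 and RP11-109P14.9 rose and CTB-131K11.1 fell, with calls lost in 4 to 6 of these fits. In all, 18 loci rose and 38 fell, and 10 of them averaged under 10 reads, among them SDCBPP3 and C16orf96, listed at 0 in all SG libraries, and AC002310.7, RP4-676J13.2, PRSS23 and RP11-875O11.2, listed at 0 in all control libraries. Of these few-read calls, that of AC002310.7 was lost in 5 and that of PRSS23 in 2 of the fits that left out a library, with limma adjusted p values up to 0.133 and 0.0735.

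Of the NF-kB target genes 0 of 64 passed in SG against control by limma, and 4 reached an unadjusted p under 0.05. Of 42 G2/M and mitosis genes ANLN fell, from 43.4 to 26.1 FPKM, and 5 fell adjusted over the list alone, with a median change of -0.13 and a camera adjusted p of 5.26e-07 (0.387 with the estimated correlation). NUF2 (35.7 to 27.2 FPKM), BUB1 (80.3 to 62.8 FPKM) and CCNB2 (83.7 to 66.6 FPKM) were lower without passing over all genes. BCL2L11 in the apoptosis list fell from 21.8 to 15 FPKM and HIST1H3H in the histone list rose from 13.6 to 22.6 FPKM, and 4 histone genes rose adjusted over the list alone. The ANLN and BCL2L11 calls were lost when any of the 6 libraries was left out and the HIST1H3H call in 5 of these fits, with limma adjusted p values up to 0.0844, 0.157 and 0.135. No other list fixed beforehand passed camera's threshold in this comparison.

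The comparison of TNFSG with TNF measured the effect of the siRNA and GapmeR in TNF-treated cells. MED1 fell from 28.7 ± 1.79 to 14.3 ± 0.40 FPKM, a change of -0.96 ± 0.07 (log2, SE) with a limma adjusted p of 0.0027. The locus shared by DNAJC25 and GNG10 fell from 49.9 ± 2.28 to 25.7 ± 0.74 FPKM and SEC11A rose from 93.7 ± 7.56 to 170.1 ± 6.58 FPKM, with limma adjusted p values of 0.00467 and 0.00734. These 3 calls held whichever library was left out. SHOC2 fell from 10.2 to 3.78 FPKM, CAST from 28.8 to 15.9 FPKM, HEATR1 from 41.5 to 23.2 FPKM and ATAD3B from 73.0 to 43.3 FPKM. UBE2L6 rose from 8.80 to 16.7 FPKM, NGDN from 20.3 to 34.8 FPKM, TM2D1 from 13.4 to 22.0 FPKM, DCTPP1 from 62.6 to 96.6 FPKM, STX12 from 12 to 18.6 FPKM and GOLGA7B from 0.55 to 2.74 FPKM. The 10 calls of SHOC2, CAST, HEATR1, ATAD3B, UBE2L6, NGDN, TM2D1, DCTPP1, STX12 and GOLGA7B were each lost in 5 or 6 of the 6 fits that left out a library, with limma adjusted p values up to 0.189 for STX12. RP11-109P14.9 rose as well, with its call lost in 5 of these fits. In all, 19 loci rose and 23 fell, and 13 of them averaged under 10 reads, among them AC012322.1, ATPIF1, EDC4, PLXNC1 and ZNF837. The ATPIF1 call was lost in 5 and the EDC4, PLXNC1 and ZNF837 calls in 6 of the fits that left out a library, with limma adjusted p values up to 0.181.

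Of the NF-kB target genes 0 of 64 passed in TNFSG against TNF by limma, and 6 reached an unadjusted p under 0.05. G2/M and mitosis genes were lower (camera adjusted p 8.91e-09, and 0.487 with the estimated correlation), with ANLN falling from 43.4 to 28.1 FPKM and 3 of 42 falling adjusted over the list alone. BCL2L11 fell from 28.2 to 18.8 FPKM. Interferon-stimulated genes were higher (camera adjusted p 0.0272, and 0.645 with the estimated correlation), with IFIH1 at 2.53 and 4.99 FPKM, IFIT5 at 0.72 and 1.90 FPKM, OAS3 at 5.78 and 9.20 FPKM and EIF2AK2 at 14.2 and 17.8 FPKM in TNF and TNFSG, none of which passed limma's threshold. Immediate early genes and integrated stress response genes each had a camera adjusted p of 0.048 for lower values, with estimated-correlation values of 0.731 and 0.645. Both of these lists had a mean change above 0 beside a median below 0. The calls of the interferon-stimulated, immediate early and integrated stress response lists were each lost in 4 of the 6 fits that left out a library, with camera adjusted p values up to 0.116, 0.914 and 0.323. BTG2 lay at 77.8 ± 12.4 FPKM in TNF and 46.5 ± 4.20 FPKM in TNFSG, with a limma adjusted p of 0.0691, and MYC lay at 185 and 134 FPKM with a limma adjusted p of 0.22. The BCL2L11 and ANLN calls were lost when any of the 6 libraries was left out, with limma adjusted p values up to 0.147 and 0.157.

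Across the comparisons of SG with control and TNFSG with TNF, which share no library, 17 loci fell in both, where independent lists would share 0.0266, and 6 rose in both, where they would share 0.0104. Here too both comparisons used the same error per locus, so the expected numbers are a reference and no test. With only the groups compared in the fit, fewer loci passed in each comparison, as given below. The 17 loci that fell in both were SHOC2, HEATR1, MED1, DNAJC25/GNG10, CAV2, CAST, CD46, ANLN, TDG, UBE2K, MFN1, PEA15, UTP6, APPL1, SLC39A14, BCL2L11 and CERS2. CD46 fell from 102.4 to 61.1 FPKM without TNF and from 90.4 to 55.1 FPKM with TNF. Those that rose in both and carried a name were RP11-109P14.9, UBE2L6, SEC11A, NGDN and NEK9. Over the 75 loci changed in either comparison, 82.7% changed in the same direction (63.1% of all loci tested), with a Spearman correlation of 0.618 and a Pearson correlation of 0.196 across genes. With loci averaging under 10 reads left out before testing, 113 loci changed in either comparison, and their correlations were 0.863 and 0.858. Of the 75 loci, 52 remained without the few-read loci and the MIR146A locus, with correlations of 0.933 and 0.982.

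**Figure D3:**
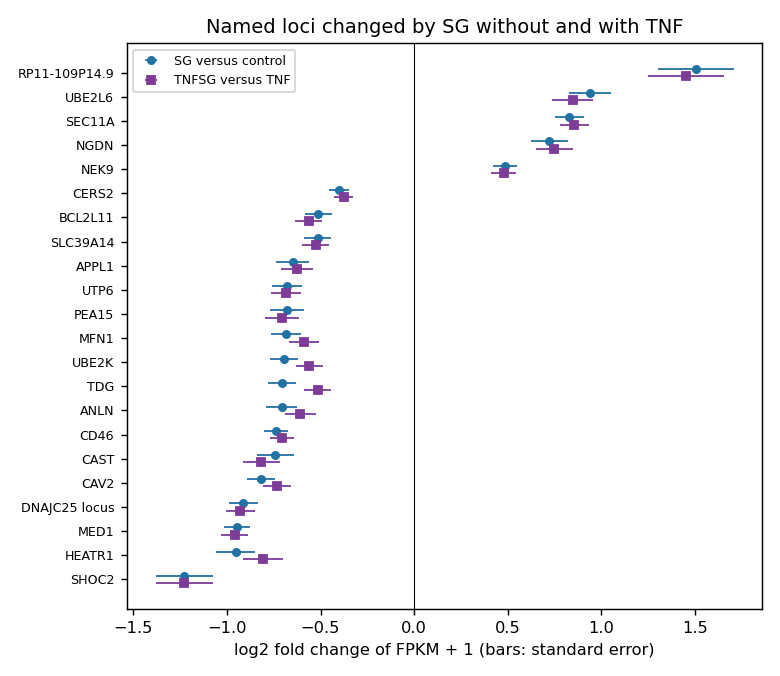
Log2 fold change of FPKM + 1 (horizontal axis) for the 22 named loci that changed in the same direction in SG versus control (circles) and TNFSG versus TNF (squares), with lines for 1 SE from limma. MED1 lies at -0.95 and -0.96 and SEC11A at 0.83 and 0.86.

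The interaction tested whether the TNF response differed between targeted and mock-transfected cells. The MIR146A locus had an interaction of -1.67 ± 0.31 (log2, SE) with a limma adjusted p of 0.47. It was -1.49 with a pseudocount of 0.5 and -0.57 with 0.1, so its size depended on the pseudocount while it stayed below 0. Without a pseudocount, the ratio of mean FPKM with TNF to that without was 68.8 in mock-transfected and 136 in targeted cells, which is the other direction. The latter ratio rests on an SG mean of 0.040 FPKM with 1 library at 0 and is not a firm fold. SDCBPP3 had an interaction of 10.74 ± 0.68, AC012322.1 of -10.36 ± 0.96 and RP4-676J13.2 of -5.76 ± 0.57, with limma adjusted p values of 0.00124, 0.0187 and 0.0218. These 3 loci averaged 5.58, 3.17 and 1.25 reads per library, and each was listed at 0 in every library of at least 1 group. With each of the 12 libraries left out in turn, the AC012322.1 call was lost in 5 fits, the RP4-676J13.2 call in 9 and the SDCBPP3 call in 0. PLXNC1 and C16orf96 had the next lowest p, with limma adjusted p values of 0.0878 and 0.092. Of the gene lists 0 passed camera's threshold, and by limma 0 of the 500 loci on any list passed, with 9 at an unadjusted p under 0.05. Over all loci 1 rose and 2 fell, and 1234 reached an unadjusted p under 0.05.

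Lists of myeloid genes, endoplasmic reticulum chaperones, cytosolic heat shock genes, cholesterol synthesis genes, histone genes and RNA silencing machinery had camera adjusted p values of 0.0735 or above in every comparison. The same held for the lymphoid and epithelial marker lists, and fibroblast and endothelial markers, with 4 and 3 tested members, had 0 members past limma's threshold in each comparison. Lists without a called member held 175 loci in TNF against control, of which 20 reached an unadjusted p under 0.05, and 414 loci in SG against control, of which 46 did. No locus in the table carried the name of a mitochondrially encoded gene.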

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

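The removal of few-read loci and the slope test of the lncRNA's own loss were chosen only after the result was seen, and the tests of values set to 0, of length and GC content, of 3 prime UTR sites and of other splits of the libraries were set before. The test of few-read loci in regrouped libraries was added after the calls were known, with its prediction written before its own result was seen. The loci named here differed between the TNF response of targeted and of mock-transfected cells by the interaction test itself. SDCBPP3 had an interaction of 10.74 (log2; limma adjusted p 0.00124), AC012322.1 of -10.36 (0.0187) and RP4-676J13.2 of -5.76 (0.0218). SDCBPP3 averaged 1317 FPKM in control, 1676 in TNF and 2298 in TNFSG and was listed at 0 in all SG libraries. AC012322.1 averaged 793 FPKM in control, 767 in TNF and 1353 in SG and was listed at 0 in all TNFSG libraries. RP4-676J13.2 averaged 63.5 FPKM in SG and was listed at 0 in the other groups. Each of the calls of AC012322.1 and RP4-676J13.2 was lost in fits that left out 1 library, with adjusted p values up to 0.0991 and 0.126.

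The 3 loci averaged 5.58, 3.17 and 1.25 reads per library, and 1 read was worth 258.5 FPKM for SDCBPP3, 232.9 FPKM for AC012322.1 and 13.2 FPKM for RP4-676J13.2. Once loci averaging under 10 reads were left out, 0 loci were called in the interaction by limma, which decides nothing because the 3 loci are themselves among those left out. In the 99 other splits of the libraries 68 distinct loci were called in the interaction, and 85.3% of them averaged under 10 reads (exact interval 74.6% to 92.7%), against 38.5% of all loci tested. Noise of few-read loci may therefore account for these calls, but calls in other splits do not show that it does. SDCBPP3 had 3 to 19 recovered reads in each library outside SG and 0 in each SG library. AC012322.1 had 1 to 12 in each library outside TNFSG and 0 in each TNFSG library. Values set to 0 for a whole group before deposit, at many loci in each group, are argued against by the numbers of loci at 0 in exactly the 3 libraries of a group. These were 15 for control, 8 for TNF, 6 for SG and 5 for TNFSG, against up to 29 and a median of 8 for the other sets of 3 libraries. The counts cannot decide this for single loci. SDCBPP3 and AC012322.1 are themselves among the loci counted, and RP4-676J13.2, at 0 in more libraries, is not covered. Of 100 splits of the libraries, 20 gave at least the 3 loci called, with up to 6 in another split, so chance is not excluded for the interaction count. A difference in the TNF response of these loci stays open.

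For the pairwise counts, 3 libraries against 3 make 10 splits, so the share of splits as large cannot go under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many. TNF against control gave 478 loci and at most 3 in another split, SG against control 56 and at most 3, TNFSG against TNF 42 and at most 5, and TNFSG against SG 540 and at most 5.

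The second pattern is the set of 17 loci that fell with the siRNA and GapmeR both without and with TNF. Gene length and GC content as the whole cause are argued against, since the median change of these genes in TNFSG against TNF was -0.69 before and -0.70 after the trend was removed. Loss of the lncRNA itself predicts a larger effect where the lncRNA is abundant, and the slope of the effect with TNF on that without TNF was 0.518 over 74 of the 75 loci changed in either comparison, the MIR146A locus being left out as the presumed target, with an interval of 0.0997 to 6.22. Whether the loss of the lncRNA is the cause cannot be told apart from other causes by this slope, because few-read loci widen its interval. With loci averaging under 10 reads left out, a choice made after that result was seen and not used to decide, the slope over 52 loci was 0.895 (0.807 to 0.999), and over the 17 loci alone it was 1.05 (0.852 to 1.29). The 17 loci were picked for a fall in both comparisons, which by itself draws their slope towards 1, so it decides nothing. The intervals come from resampling loci, which are not independent replicates. Off-target binding through the seed of an siRNA may contribute, as the strongest 7-base site in SG against control ranked 2 of 16099 in TNFSG against TNF, and its details are under the other observations.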

How the results depend on the processing

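Robust empirical Bayes, the restriction to protein-coding genes and the removal of loci averaging under 10 reads were chosen only after the result was seen, and the other alternatives were planned. Of 139 called results for named genes, 51 kept their call in every setting and 88 lost it in at least 1, while 15 of 86 uncalled ones gained a call. Of 19 called list results, 6 kept their call in every setting: NF-kB targets, interferon-stimulated genes and apoptosis genes in both TNF comparisons. No called named gene changed direction, and uncalled values that changed sign were not counted. The cause of the changes below was not tested, except that fits with fewer libraries or groups have fewer degrees of freedom.

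With only the groups compared in the fit, the counts were 172 in TNF against control (478 with all libraries), 7 in SG against control (56), 2 in TNFSG against TNF (42) and 256 in TNFSG against SG (540), and 82 of 136 named calls were lost. The fall of the MIR146A locus in TNFSG against TNF then had a limma adjusted p of 0.214, and 0.0968 with a pseudocount of 0.1. In TNF against control 431 loci rose and 191 fell with the filter at 5 FPKM, 443 and 162 among protein-coding genes, 525 and 174 without few-read loci, and 344 and 46 without the trend, against 387 and 91. In TNFSG against SG 401 rose and 156 fell, 443 and 148, 544 and 177, and 403 and 51 in the same order, against 449 and 91. Without the trend, 16 loci passed in SG against control (7 rose and 9 fell) and 18 in TNFSG against TNF (11 rose and 7 fell). By median-ratio scaling 83 loci passed in SG against control (17 rose and 66 fell, against 18 and 38) and by quantile normalization 62 (13 rose and 49 fell). With the filter at 5 FPKM the counts were 115 and 97 (34 rose and 63 fell in the latter), and among protein-coding genes 94 and 95, where fewer loci share the adjustment. For TNFSG against TNF, removing few-read loci gave 95, robust empirical Bayes 64, and median-ratio scaling 78 (19 rose and 59 fell, against 19 and 23), and quantile normalization gave 63 (17 rose and 46 fell). The interaction count was 12 with a pseudocount of 0.1 and 0 by limma both among protein-coding genes and without few-read loci, against 3 loci and 1234 at an unadjusted p under 0.05.

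Leaving out each library in turn gave counts of 294 (without control replicate 2) to 432 for TNF against control, 10 (without control replicate 2) to 29 for SG against control, 7 (without TNF replicate 3) to 18 for TNFSG against TNF, 311 (without TNFSG replicate 1) to 364 for TNFSG against SG, and 1 to 6 for the interaction. Lists called ranged from 6 to 8, 1 to 4, 1 to 5, 7 to 8 and 0 to 2 in the same order. Immediate early genes in TNFSG against TNF changed direction without TNF replicate 1 (camera adjusted p 0.914) and ran from 0.00171 without TNF replicate 2 to that value.

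With an estimated correlation, camera called 3 lists in TNF against control (7 with the preset correlation), 0 in SG against control (1), 0 in TNFSG against TNF (4) and 3 in TNFSG against SG (7). By fry 0 lists passed in TNFSG against TNF, and in SG against control 1 passed, the TNF receptor signalling components (adjusted p 0.00655), which camera had not called (0.0941), while the G2/M list had 0.141 by fry, and with a pseudocount of 0.1 camera called 2 lists in SG against control.

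Deviations of same-numbered samples correlated by 0.0065 to 0.138 over 18 pairs, 1 above 0.1 (median 0.0225, others -0.0165). The own number correlated best in 28 of 36 checks. This points to a shared replicate effect, not in the main model. By these correlations it was small over all loci, but single loci such as HBZ rose with the replicate number in every group. With the replicate number as a block, 831 loci changed in TNF against control (592 rose and 239 fell) and 843 in TNFSG against SG (638 rose and 205 fell), while 71 changed in SG against control, 59 in TNFSG against TNF and 2 in the interaction. Under the block camera called 3 lists in SG against control. The agreement of the TNF response under the block was 0.822 (Spearman) and 0.630 (Pearson), and that of the SG effect 0.715 (Spearman) and 0.143 (Pearson).

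The agreement of the TNF response was 0.244 (Spearman) and 0.189 (Pearson) over all loci tested and 0.894 and 0.881 without few-read loci, and over libraries left out it ran from 0.710 to 0.801 and from 0.459 to 0.581. The agreement of the SG effect was 0.196 (Spearman) and 0.104 (Pearson) over all loci tested and 0.863 and 0.858 without few-read loci. Over libraries left out it ran from 0.206 to 0.650 (Spearman) and from -0.034 without control replicate 3 to 0.245 (Pearson).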

Other observations

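The counts of sites among the genes that fell, the position of the site in the host transcript and the gene lists below were chosen only after the result was seen, and the rank tests of sites were set before. The lists hold genes already seen to change, so they are not independent evidence.

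Among 16099 sites of 7 bases in the 3 prime UTRs of 8519 genes, genes with ACTTTAA (1806 genes) had the lowest z score, the shift in mean change divided by its error, in SG against control (-6.04), and this site ranked 2 of 16099 in TNFSG against TNF, where the overlapping CACTTTA (1380 genes) ranked 1. In TNFSG against TNF the site TTTAACT ranked 3, with a z score of -4.79 close to the -4.81 of ACTTTAA. The site GCACTTT, which overlaps CACTTTA and pairs with the miR-17 family, ranked 124 in SG against control and 19 in TNFSG against TNF. Over all sites the z scores of these comparisons correlated by 0.422, so shared sequence trends also favour a high rank in both. Off-target binding of an siRNA through its seed may contribute to the genes that fell. The siRNA and the GapmeR were always given together, so their effects, on the target or off it, cannot be told apart here. Of the 17 loci that fell in both comparisons 12 had ACTTTAA or CACTTTA, and MED1, HEATR1, TDG, CAST and DNAJC25 had neither, while 27.8% of other genes had 1 or both. The full CACTTTAA was in 2 of the 17, CERS2 and UTP6, and in 6.17% of other genes. The site was picked from the same comparisons as these loci, so these counts are a description and no test. The other genes were not matched for the length of the 3 prime UTR, and a longer UTR holds any given site more often. Whether the 17 loci had the site more often than genes with UTRs of similar length was not tested. After the trend was removed, the 527 genes with CACTTTAA lay at -0.09 ± 0.02 (mean, SE) in SG against control and -0.05 ± 0.02 in TNFSG against TNF. Before its removal their median change was -0.068 and -0.025, against 0.060 and 0.053 for genes with neither 7-base site. The shift per gene was thus small.

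The CACTTTAA sequence occurs at bases 640 to 647 of the 2301 bases of MIR3142HG-201, and the stretch from base 623, the number in the siRNA's label, to its end is 25 bases long. In the other transcript, MIR3142HG-202 of 2204 bases, the sequence lies at bases 543 to 550, so base 623 comes after it. A given 8-base sequence occurs in MIR3142HG-201 with a chance of 3.38% and in MIR3142HG-202 with 3.25%, and a given tested 7-base site with 12.7% and 12.1%. That an siRNA against that stretch might carry this seed is only a hypothesis beside the rank of 2 given above, and it rests on the first of these transcripts. The siRNA sequence was not used here, and whether the number counts bases of this transcript is not given in the sources used here.

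Less miR-146a-5p after the loss of its host transcript would raise genes with the site AGTTCTC. In TNFSG against TNF the 1130 genes with that site lay at percentile 39.8 among all sites, so no rise of these genes was seen. In TNF against control they were not clearly lower either (z score -0.88, rank 2838 from the lowest of 16099 sites). With little lowering by TNF to undo, the test cannot decide whether less miR-146a-5p was present. Mature miRNA was not measured in these libraries.

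Of 52 ribosome synthesis genes 10 fell in TNF against control and 49 were lower (camera adjusted p 3.98e-19, and 0.0317 with an estimated correlation), and 9 fell in TNFSG against SG (0.0669 with an estimated correlation). The list was also lower with the siRNA and GapmeR, with 40 of 52 genes lower in SG against control (camera adjusted p 5.59e-09, and 0.125 with an estimated correlation) and 36 in TNFSG against TNF (0.000115 and 0.28). POLR1B fell from 23.6 to 13.9 FPKM and RRP1B from 32.9 to 22.8 FPKM in TNF against control. Of 17 class I antigen presentation genes 6 rose in each TNF comparison (0.00167 and 0.00183 with an estimated correlation), with B2M at 279 FPKM in control and 372 FPKM in TNF and ERAP2 at 2.25 and 8.35 FPKM. With the siRNA and GapmeR 14 of the 17 were higher in SG against control and 15 in TNFSG against TNF (0.125 and 0.17 with an estimated correlation). The median change of all tested loci was itself above 0 in these comparisons, at 0.085 and 0.081, against 0.211 and 0.251 for this list. Part of these counts of higher genes therefore goes with the shift of all loci. All 6 loci named CYP3A5 rose in both TNF comparisons, by 2.31 to 3.08 (log2) in TNF against control. HBZ was lowest in replicate 1 in 4 of 4 groups, with 295, 842 and 1160 FPKM in the control libraries. The locus shared by HBE1 and HBG2 was also lowest in replicate 1 in 4 of 4 groups, and HBG1 in 1 of 4, while over all loci the same-numbered samples correlated by 0.138 at most.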
